A study of Mus musculus with 2 samples.

How the data were processed

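DNase-seq was measured in heart tissue of 2 female B6CASTF1/J mice at an age of 4 days, with 1 library per animal. The labels name them biological replicates 1 and 2 of 1 experiment, and they form 1 group without a control or a treatment. The only comparison between samples is therefore heart against heart, and the other comparisons are between sites, genes and motifs within the hearts.

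The authors deposited 4 interval files per library on the mm10 assembly and a text file that names them. A pair of peak lists per library give positions and a peak signal, which per the labels of the files was made from the filtered alignments of that library. The deposited signal is a whole multiple of 1 step per library, the same step in both lists, with a tolerance of 0.05 of a step and 100% of values within it. It is thus a whole number times a factor per library that the authors do not state, so signals were compared between hearts by rank, as percentiles or a rank correlation, and a signal given for a single site keeps the factor of its library. The deposited false discovery rate of each stretch of DNA is a p-value type unit adjusted by the authors, and only stretches under 0.05 are listed. The deposited footprint files hold positions only, because their other value is 0.01 throughout. Peak caller, footprint caller and their versions are not given in the sources used here. Every site of the longer peak list touched DNA at a rate under 0.05 and every site of the shorter list DNA at a rate of 0.001 or less.

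The main list of each heart was the one with the narrower sites, which was also the longer one: its mean width was 213.2 bp against 213.7 bp in heart 1 and 192.5 bp against 194.8 bp in heart 2. The rule therefore decided between nearly equal widths. The other list, with 115050 and 112959 sites, served as an alternative. Read or cut totals are not in the files, so no depth and no detection limit could be given, and shares carry exact (Clopper-Pearson) binomial intervals at 95% that cover counting error only. The inverse of the signal step was 1.37 times as large in heart 2 as in heart 1.

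Gene positions came from GENCODE M21 and sequence from the RefSeq copy of the same assembly. Coordinates are counted from 1. A site was shared where it overlapped a site of the other heart by at least 1 bp, and overlapping sites were joined into regions. Chance overlap came from 20 seeded shuffles of the sites within their chromosomes. A region was at a promoter within 500 bp of any annotated transcription start, otherwise in an exon, an intron or between genes, and distal when more than 2 kb from every start. A distal region was given to the protein-coding gene with the nearest start within 100 kb. The overlap code was written for this purpose and checked against bedtools 2.31.1, which gave the same counts on 5 of 5 simulated sets and on the deposited lists (135710 and 137419).

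Before the data were examined, 26 gene lists were fixed for the parts and cell types of the heart, for stages, metabolism and cell cycle, for other organs and for housekeeping. They hold 407 entries, of which 405 matched a protein-coding gene (H19 and Ahsp did not), and some genes stand in more than 1 list, such as 9 of the 25 contractile genes. Each list had 3 tests, adjusted over the lists by Benjamini and Hochberg. Promoter accessibility was compared with all other protein-coding genes by Fisher's exact test, two-sided, and with 10000 random lists of the same size matched on the CpG ratio of the promoter in 10 bins. Numbers of distal sites were compared with 10000 random lists matched in 20 bins on the length of DNA whose nearest start is the gene's. Promoter strength was the percentile of the strongest promoter site among the sites of its heart, 0 without a site, averaged over the hearts and compared with CpG-matched random lists, as was the difference between the hearts. These random-list tests are permutation tests of list membership over genes, with two-sided p-values. In 2552 of the 15161 genes with a promoter site, the strongest site also lay at another coding gene.

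Genes named in the text followed a rule fixed at the same time: in each list up to 4 members with the highest mean promoter percentile, up to 4 with the most shared distal sites and up to 4 (alphabetical) without a promoter site in either heart, any member of the contractile and cardiac transcription factor lists, the 10 genes with the most distal sites, the 10 strongest shared sites and the 5 strongest sites of each heart alone. For motifs it took the 6 highest, the 3 lowest and all of heart factors. A few of the genes and motifs that the rule takes are not reported here, although counts and means over lists and motifs include them. ETS, USF, YY1, TEAD, PU.1, AP-1 and RUNX motifs and the Y sites were named after their values were seen.

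For 38 motifs, consensus sequences written down beforehand were matched on both strands without mismatch. Matches per kb with their centre in footprints were compared with the rest of the same sites as a log2 ratio per heart, averaged over the hearts, and with up to 50 shuffled versions of the consensus, one-sided. A set of 3 motifs (PPAR/RXR, P63 and HNF1) had fewer than 20 matches and was left out of the counts. The GC-rich SP/KLF consensus allows only 7 distinct shuffles. After the data were seen, up to 1000 shuffles were run for the 31 motifs of at most 12 bases, both in footprints and in distal shared regions against flanking DNA at a distance of 1000 bp.

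On simulated data, 200 lists of 16 genes drawn at random gave p under 0.05 in 5% (Fisher), 3% (CpG-matched), 5.5% (distal) and 5.5% (strength) of cases, and lists with a planted excess in 100%, 97.5%, 88% and 99.5%. A planted motif with a log2 ratio of 5.39 was recovered at 5.26. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.

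Alternatives fixed beforehand were the other peak list, the stronger 50% of sites, equal numbers of sites, a reciprocal overlap of 50%, promoter windows of 250 and 1000 bp, only the 5'-most start of a gene, assignment within 50 or 500 kb, distal beyond 5 kb, no matching on length, summed promoter signal, footprints widened by 5 bp, background within 50 bp of a footprint, distal sites only, and each heart alone. Alleles of the parent strains were not separated, since the files hold no reads, and sequence matches used the reference assembly only.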

Results

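DNase-seq, which maps accessible chromatin by the places where the enzyme DNase I cuts nuclear DNA, was run on the hearts of 2 female mice at an age of 4 days. The animals were B6CASTF1/J, a hybrid of an inbred laboratory strain and the wild-derived CAST strain. They form 1 group, neonatal heart, with 1 library from each animal, called heart 1 and heart 2 here. Heart 1 had 178133 accessible sites with a median width of 200 bp, which covered 37.3 Mb of the mm10 assembly. Heart 2 had 177096 sites with a median width of 180 bp, which covered 33.6 Mb. The median peak signal of a site was 0.593 in heart 1 and 0.574 in heart 2. The files give no read or cut totals, so the depth of each library is unknown. All signals were whole multiples of 1 step per library, within a tolerance of 0.05 of a step, and the step was 0.00516 in heart 1 and 0.00378 in heart 2. With 1 library per heart there is no replicate of either animal, genes and sites are not replicates, and no p-value compares the animals. Intervals cover counting error only.

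The strongest accessible site of both hearts lay on chromosome 17 from 39846781 to 39846920, at the non-coding genes Gm26917 and Gm42418, with a signal of 68.2 in heart 1 and 66.6 in heart 2. The genes AY036118 and CT010467.1 lay within 500 bp of it too. A pair of sites in an intron of Mid1, a microtubule-associated ubiquitin ligase, on chromosome X were also among the 10 strongest by mean percentile, and the stronger of them spanned 169997961 to 169998240 with signals of 59.2 and 56.9. The promoters of Hjurp, the chaperone of the centromeric histone, on chromosome 1, of Dynlt1b, a dynein light chain, on chromosome 17, of Mplkip on chromosome 13 and of Nup107, a nuclear pore subunit, on chromosome 10 belonged to the same set. The others lay in an exon of Lars2, the mitochondrial leucyl-tRNA synthetase, on chromosome 9, at the pseudogene 2610005L07Rik on chromosome 8, and in an exon close to the start of Kpna1, an importin, on chromosome 16. In 7 of these 10 sites, the 31-base words of the sequence had a median of more than 1 copy in the assembly, against 2% of 1000 shared sites drawn at random. Among the 7 was the strongest site, with 82.7% of its words in more than 1 copy.

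Of the sites of heart 1, 135710 (76.2%) overlapped a site of heart 2 by at least 1 bp, and 137419 sites of heart 2 (77.6%) overlapped a site of heart 1. Random placement on the same chromosomes gave an overlap of 2.82% on average and 2.89% at most in 20 shuffles. Joined over the hearts, the sites made 213656 regions, of which 132616 (62.1%) held sites of both, 41786 of heart 1 alone and 39254 of heart 2 alone. Across the shared regions, the signals of the hearts had a Spearman correlation of 0.939, a value across sites that are not independent. Sharing followed strength: in heart 1, 26.4% of the weakest decile of sites and 99.8% of the strongest were shared, and in heart 2 23.7% and 99.1%. An overlap of at least 50% of both sites was met by 65.6% of the sites of heart 1 and 66% of those of heart 2.

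Sites called in 1 heart only were mostly weak. Their median percentile within their own heart was 17.8 in both, against 61.6 for the shared sites of heart 1 and 59.9 for those of heart 2. The strongest site of heart 1 alone was at the promoter of Tarbp2, a partner of Dicer, on chromosome 15 from 102518281 to 102518520 with a signal of 12.5. It was followed by sites at the promoters of Opa3, a mitochondrial protein, of Zfp335, a zinc finger factor, and of Trappc4, a vesicle tethering subunit, and by a site at the promoter of a non-coding gene, with Smim15 as the nearest coding gene. In heart 2 alone, the strongest was at Rbpj, the DNA-binding effector of Notch signalling, on chromosome 5 from 53590581 to 53590740 with a signal of 11.7, followed by sites at Cactin, Esyt2, Tmem143 and Pgrmc2. Sites of this strength were rare among those without overlap: 33 in heart 1 and 163 in heart 2 were in the strongest decile of their heart, and 190 of these 196 had a site of the other heart within 200 bp.

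Promoters held 29364 of the 132616 shared regions (22.1%, exact binomial 95% interval 21.9 to 22.4), counted as regions within 500 bp of an annotated transcription start. Random positions of the same width gave 4.06%, so promoters were 5.45-fold over random. Introns held 39.9% of the shared regions against 40.3% at random, the space between genes 32.1% against 51.9%, and exons outside promoters 5.79% against 3.65%. The share at promoters was 9.43% in the weakest decile of shared regions and 71.4% in the strongest. Regions farther than 2 kb from any transcription start, called distal here, numbered 87622 (66.1%). Among regions of 1 heart only, 9.12% of those of heart 1 and 15.1% of those of heart 2 were at promoters.

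**Figure D1:**
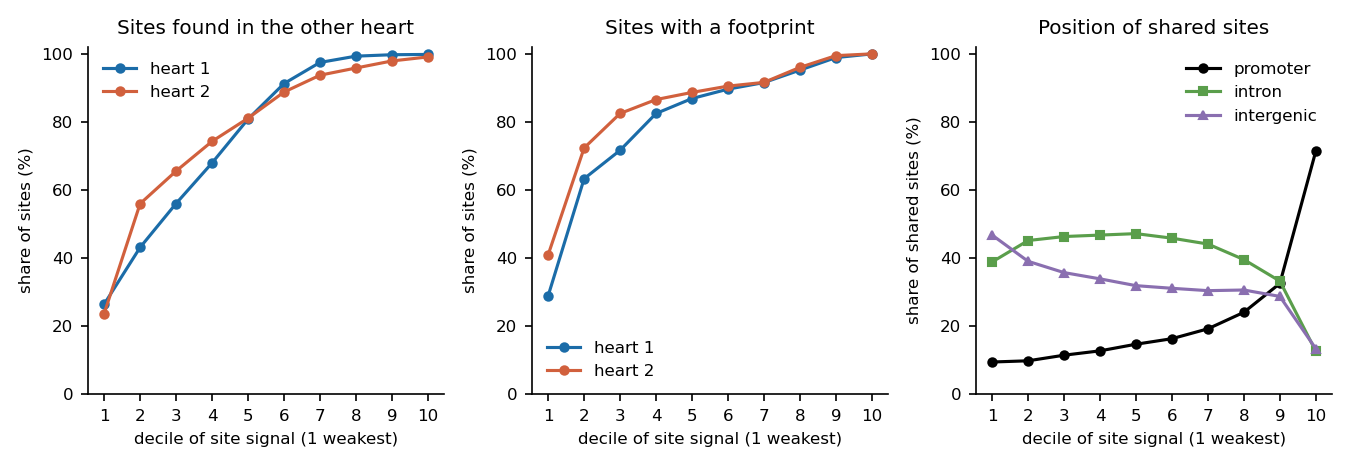
Share of sites found in the other heart (left), share of sites with a footprint (middle) and genomic position of shared sites (right), in percent, against the decile of site signal from 1 (weakest) to 10 (strongest). Points are single hearts on the left and in the middle, where both lines climb with signal, and all shared sites on the right, where promoters reach 71.4% in the strongest decile.

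Autosomes had 70.5 sites per Mb in heart 1 and 70.0 in heart 2, from the fewest on chromosome 3 (56.6 and 55.9) to the most on chromosome 11 (99.3 and 100.5). Chromosome X had 25.96 and 26.5 sites per Mb. The labels give both animals as female, and chromosome Y had 53 sites in heart 1 and 83 in heart 2, or 0.578 and 0.905 per Mb. The strongest Y site spanned 90744601 to 90744820, with a signal of 7.01 in heart 1 and 10.5 in heart 2, and belonged to a cluster that began at 90717601. Outside that cluster, Y regions had a median percentile of 0.0109 in heart 1 and 0.115 in heart 2, among the weakest of each list. Within the cluster the medians were 37.5 and 64.8. Regions at the Y genes Kdm5d, Uty, Ddx3y and Usp9y were at percentile 0.115 or lower. Of the 93 Y regions of either heart, 62 had at least 50% of their 31-base words on another chromosome too.

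The promoters of all 25 genes of the contractile apparatus were accessible in both hearts. The strongest promoter sites of the list, by mean percentile among the sites of each heart, were at Myom1, an M-band protein (99.8), Myl4, the atrial essential light chain (99.6), Tpm1, a tropomyosin (99.1), and Actn2, the alpha-actinin of the Z disc (96.0). The sites of Myom1 and Myl4 also lay at the promoters of the neighbouring genes Myl12a and Cdc27, so the signal cannot be given to 1 gene. Actc1, cardiac actin, had percentiles of 96.3 in heart 1 and 95.5 in heart 2, Tnnt2, cardiac troponin T, 92.5 and 90.03, Ttn, the giant protein titin, 93.1 and 92.2, and Myl2, the ventricular regulatory light chain, 92.6 and 89.4. Myl7, the atrial regulatory light chain, was lower, with 62.4 and 59.7.

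Cardiac transcription factors had an accessible promoter in both hearts in 21 of 22 cases. Hey2, a Notch target of ventricular muscle (99.5), Tead1, an effector of Hippo signalling (99.1), Mef2a, a MADS-box factor of muscle (98.8), and Srf, the serum response factor (98.2), had the highest mean percentiles. Gata4 reached 95.9 in heart 1 and 95.5 in heart 2, Nkx2-5, the homeobox factor of the heart, 92.6 and 89.2, and Tbx5, a T-box factor of the atria and left ventricle, 79.2 and 64.9. Hand1 was the exception, with no promoter site in heart 1 and a site at percentile 27.6 in heart 2.

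Both stage lists were fully accessible: 14 of 14 genes of the neonatal heart and 13 of 13 of the adult heart. Igf2bp3, an RNA-binding protein of fetal tissues, had a mean percentile of 95.7, Slc2a1, the glucose transporter of fetal heart, 94.7, and Acta2, smooth muscle actin, 90.2. On the adult side, Ppara, the nuclear receptor that drives fat burning, had 98.7, Slc2a4, the insulin-dependent glucose transporter, 98.6, Pdk4, a brake on pyruvate oxidation, 96.5, and Ckm, muscle creatine kinase, 95.7. The promoters of fatty acid oxidation (22 of 22) and glycolysis (18 of 18) were accessible throughout, with Esrra, a nuclear receptor of mitochondrial genes, at 99.96, Acsl1, an acyl-CoA synthetase, at 99.8, Hk1, a hexokinase, at 99.5, and Eno1, an enolase, at 98.8. So were those of 19 of 19 cell cycle genes, such as Ccne1, cyclin E (99.8), Cdk4 (99.4) and Mki67, the proliferation marker (96.6), and 17 of 17 housekeeping genes. Calcium handling and ion channels had 18 of 20, with Kcnj2, an inward rectifier (96.9), Atp2a2, the calcium pump of the sarcoplasmic reticulum (96.6), and Ryr2, the calcium release channel (92.1), and no promoter site at Sln, the pump inhibitor sarcolipin. Atrial genes had 10 of 12, without Sln and Bmp10, and ventricular genes 9 of 10.

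Genes of the other cell types of the heart were accessible as well. All 19 endothelial genes had promoter sites in both hearts, from Vwf, von Willebrand factor (95.8), Esam, a junction protein (91.1), and Eng, endoglin (90.2), down to Erg, an ETS factor (45.1). All 16 fibroblast genes had them, with Fn1, fibronectin (97.2), Pdgfra, a PDGF receptor (95.6), and Col1a1, collagen I (95.5), as did all 14 genes of smooth muscle and pericytes, with Smtn, smoothelin (96.8), Des, desmin (94.8), and Myh11, smooth muscle myosin (92.2). Of 11 epicardial genes 9 did, including Tbx18 (94.5) and Sema3d (91.5).

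Among genes of blood lineages and other organs the shares varied. Macrophage genes were accessible in 4 of 15 cases, with Irf8 at 94.7 and no promoter site at Adgre1, the F4/80 antigen, C1qa, Cd163 or Csf1r, the receptor of the macrophage growth factor CSF. Lymphoid genes had 3 of 14, with none at Cd3e, Cd3g or Cd4, and erythroid genes 7 of 14, with none at Alas2, Epb42, Gata1 or Hba-a1. Hba-a1 and the Hbb genes have near-identical copies in the assembly, so their absence is uncertain. Skeletal muscle genes had 7 of 18, with none at Myf5 and Myf6, factors that specify skeletal muscle, Myh1, a fast myosin, or Atp2a1, the fast calcium pump, while Mylpf, fast myosin light chain (97.8), shared its site with Tbc1d10b. Hepatocyte genes had 2 of 15, Foxa1 (41.7) and Foxa2 (30.4), with none at Alb, albumin, Afp, Apoa1 or Cps1. Germline and pluripotency genes had 3 of 12, with none at Ddx4, Dppa3, Nanog or Pou5f1. Schwann and autonomic genes had 6 of 12, neuronal genes 13 of 15, pancreas and gut 7 of 14, retina and lens 6 of 12, and epithelial genes 9 of 12.

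Over the whole genome, 15161 of 21911 protein-coding genes (69.2%) had a promoter site in both hearts. By Fisher's exact test (two-sided, Benjamini-Hochberg over 26 lists), 11 lists lay above other genes: contractile (adjusted p = 0.00165), cardiac transcription factors (0.0103), neonatal stage (0.0146), adult stage (0.0215), fatty acid oxidation (0.00416), glycolysis, cell cycle and endothelial (0.00561 each), fibroblast (0.0103), smooth muscle and pericytes (0.0146) and housekeeping (0.00717). A set of 5 lay below: macrophage (0.00448), lymphoid (0.00276), skeletal muscle (0.0154), hepatocyte (0.000311) and germline (0.00601). The other 10 lists were not called (adjusted p from 0.0780 to 0.766). The share followed the CpG content of the promoter, from 3.88% of genes in the decile with the lowest CpG ratio to 99.1% in the highest. In a permutation test against random lists of like CpG content, contractile promoters stood at 100% against 51.4% (adjusted p = 0.00173), and neonatal stage, adult stage, fatty acid oxidation, endothelial, fibroblast, smooth muscle and calcium handling (adjusted p = 0.0499) lay above. In the same permutation test, hepatocyte (13.3% against 43.5%, adjusted p = 0.0162) and germline genes (25% against 72.0%, adjusted p = 0.00173) lay below. The calls of cardiac transcription factors (adjusted p = 0.914), glycolysis (0.717), cell cycle (1), housekeeping (1), macrophage (0.960), lymphoid (0.303) and skeletal muscle genes (0.0539) ended in this permutation test.

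Of the calls against random lists of like CpG content, that of calcium handling was lost with a window of 1000 bp (adjusted permutation p = 0.103), the 5'-most start (1), the stronger 50% of sites (0.189) and in heart 2 alone (0.0771). That of hepatocyte genes was lost with 1000 bp (0.218), the 5'-most start (0.0837) and in heart 2 alone (0.0603), and that of endothelial genes with the 5'-most start (adjusted permutation p = 0.179). For cardiac transcription factors, glycolysis, cell cycle and housekeeping, random lists averaged 91.0, 93.0, 97.1 and 96.6% and reached 100% within their 95% range, so no share could have been called above them. With the shorter peak list and with the stronger 50% of sites, skeletal muscle (0.0457 and 0.0284), neuronal (0.0269 and 0.00425), pancreas and gut (0.0227 and 0.0453) and epithelial genes (0.0436 and 0.00104) were called below random lists in the permutation test, as were retina and lens genes in the stronger 50% (0.0147). With the 5'-most start pancreas and gut (0.00312) and retina and lens genes (0.0156) were below, and in heart 2 alone epicardial genes were above (permutation, 0.0175). By the exact test, counting only the 5'-most start of each gene ended the calls of the endothelial (0.319), fibroblast (0.107), glycolysis (0.424) and adult stage lists (0.0697). A window of 250 bp ended those of neonatal stage (0.0707) and fibroblast genes (0.0508), the shorter peak list the same pair (0.0678 and 0.159), and a window of 1000 bp that of skeletal muscle (exact test, 0.473). In heart 1 alone skeletal muscle was not called (0.252) and calcium handling was (0.0240), as it was with the shorter list (exact test, 0.0498). The exact test also called pancreas and gut below other genes with the 5'-most start (0.00570) and the shorter list (0.0413), retina and lens with the 5'-most start (0.0257) and the stronger 50% (0.0185), and epithelial genes in the stronger 50% (0.000659).

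Contractile genes had 6.88 shared distal sites each (SD 6.34, 25 genes), against 3.44 in random lists matched on the length of DNA nearest to each gene, with 25 at Ttn, 18 at Tnnt2 and 16 at Ldb3, a Z-disc protein. Cardiac transcription factors had 11.8 (SD 10.4, 22 genes) against 6.45, with 44 at Prdm16, 32 at Tead1, 22 at Gata4 and 19 at Gata6. Endothelial genes had 9.84 against 5.16, with 20 each at Pecam1, a junction adhesion molecule, and Flt1, a VEGF receptor, 19 at Erg and 17 at Kdr, the main VEGF receptor. Ventricular genes had 8.20 against 3.55, with 16 at Irx5 and 13 at Lbh, and neonatal stage genes 7.29 against 3.61, with 17 at Ankrd1, a stress-responsive ankyrin protein, and 17 at Igf2bp3. Smooth muscle and pericyte genes had 5.36 against 2.49, with 11 at Cspg4 and 10 at Notch3. Cell cycle genes had 4.53 against 2.35, with 20 at Ccnd1 and 17 at Ccnd3, both D-type cyclins, while 10 of the 19 had none. The genes with the most in the whole genome were Pde4d, a cAMP phosphodiesterase, with 78, Zmiz1 with 69, Tns1, tensin, with 67, Gse1 with 66, Kalrn with 63, Nav2 with 61, Bach2 with 56, Sh3pxd2a with 53, Frmd4a with 52 and Nedd4l with 50, against a median of 1 over all genes. This ranking is not matched on the length of DNA nearest to each gene. Among the genes named, that length ran from 215 kb at Sh3pxd2a to 1565 kb at Pde4d.

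These 7 lists had more distal sites than the matched random lists (two-sided permutation test, 10000 random lists, adjusted p = 0.0156 for contractile, cardiac transcription factors, neonatal stage and endothelial, 0.0182 for cell cycle and smooth muscle, 0.0193 for ventricular), and no list had fewer. The lowest ratio was 0.643 for pancreas and gut (adjusted permutation p = 0.403), and at an unadjusted p under 0.05 there was also no list below. The other 19 lists had adjusted permutation p from 0.0797 to 0.886, among them fibroblast (0.0874), adult stage (0.140), calcium handling (0.152), atrial (0.466) and epicardial genes (0.805). Housekeeping genes, not called either (adjusted permutation p = 0.0936), had 3.18 sites against 1.65. Their ratio of 1.93 was above the 1.83 of cardiac transcription factors, so a ratio of this size is not particular to lists of the heart. With distal set to more than 5 kb from any start, each of the 7 had an adjusted permutation p of 0.0643, so none was called, at ratios from 1.63 for cardiac transcription factors to 2.27 for ventricular genes. Cell cycle was not called within 50 kb (0.0630), within 500 kb (0.0527) or in the stronger 50% of sites (0.0537), nor ventricular within 500 kb (0.0565). In heart 2 alone neonatal stage (0.0557), smooth muscle (0.0557) and cell cycle (0.0739) were not called and calcium handling was (0.0395), in heart 1 alone fatty acid oxidation was called as well (0.0325), and without matching on length cell cycle (0.531), smooth muscle (0.419), ventricular (0.0942) and neonatal stage (0.0942) were not, while calcium handling (0.00347), fibroblast (0.0247) and fatty acid oxidation (0.0364) were. Glycolysis was called with the shorter peak list (0.0325) and in the stronger 50% of sites, where calcium handling was too (adjusted permutation p = 0.0423 each). Counting all sites of a single heart, contractile genes had 12.1 in heart 1 and 11.5 in heart 2, against 4.61 and 4.51 in random lists, and ventricular genes 11.6 and 13.5, against 4.70 and 4.67.

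**Figure D2:**
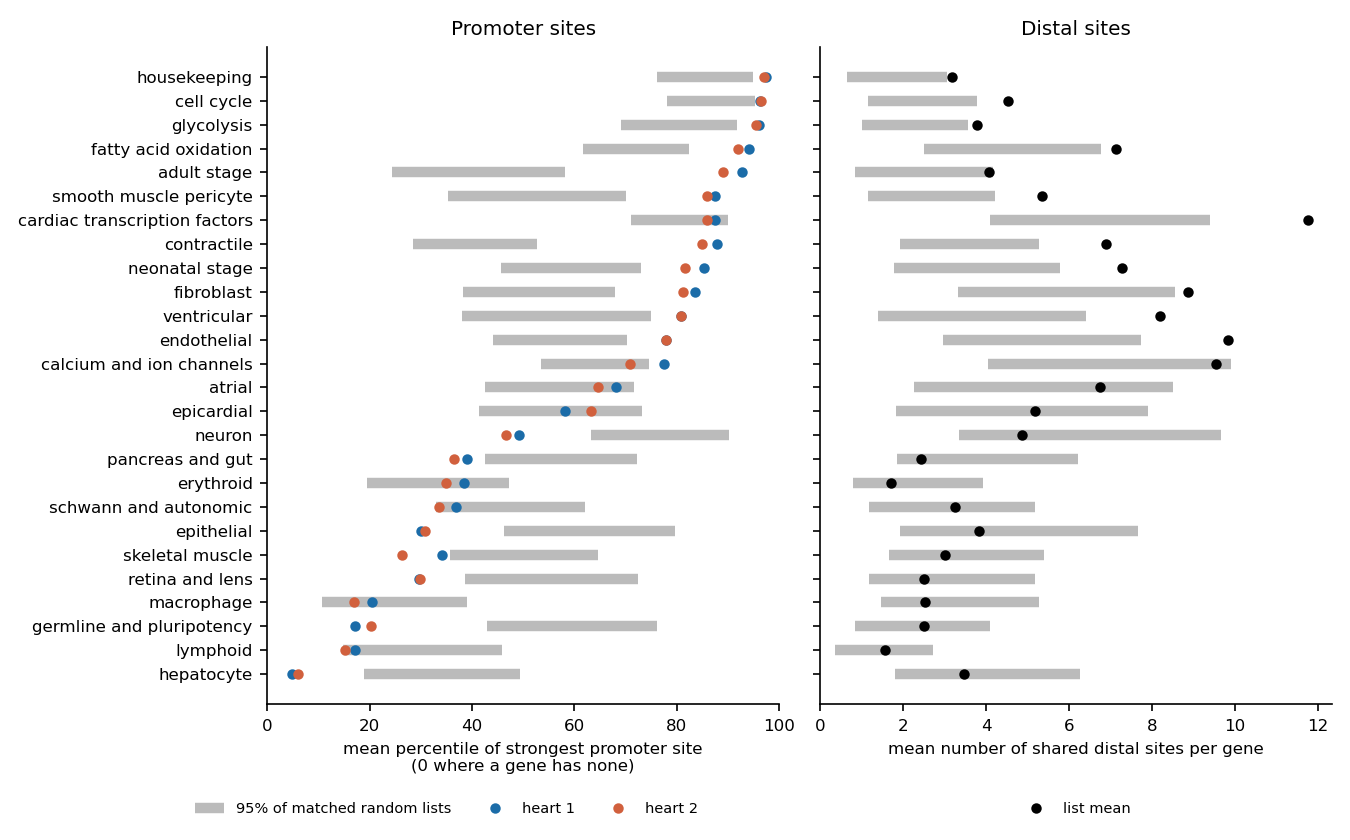
Left, mean percentile of the strongest promoter site of each gene list in heart 1 and heart 2, on a scale from 0 to 100, and right, mean number of shared distal sites per gene; grey bars span the middle 95% of 10000 matched random lists. Contractile promoters average 86.4 over the hearts and hepatocyte promoters 5.41, and cardiac transcription factors have the most distal sites, 11.8 per gene.

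The mean percentile of the strongest promoter site, with 0 for a gene without one, was 86.4 for contractile genes (SD 11.03, 25 genes) against 40.3 in random lists of like CpG content, and 90.9 for adult stage genes (SD 6.42, 13 genes) against 40.9. Fatty acid oxidation had 93.0, smooth muscle and pericytes 86.7, neonatal stage 83.5, fibroblast 82.4, ventricular 80.8 and endothelial genes 77.9, and glycolysis, cell cycle and housekeeping genes had 95.8, 96.4 and 97.2. All 11 lay above their random lists (adjusted p from 0.000578 to 0.0135). A group of 7 lay below: hepatocyte (5.41 against 33.4), germline (18.7 against 59.7), retina and lens (29.7), skeletal muscle (30.3), epithelial (30.4), pancreas and gut (37.7) and neuronal genes (48.0 against 77.7), with adjusted p from 0.000578 to 0.0173. The smallest unadjusted p that 10000 random lists can give is 0.0002, which 9 of the lists above or below reached. Cardiac transcription factors, at 86.7 against 81.2, were not called (adjusted permutation p = 0.282), nor were calcium handling, atrial, epicardial, macrophage, lymphoid, erythroid and Schwann genes. Ranked by the summed signal of all promoter sites, neonatal stage (0.134), cell cycle (0.111) and endothelial genes (0.194) were not called, with a promoter window of 1000 bp skeletal muscle was not (0.405), and calcium handling was called above with that window (0.0448) and in heart 1 alone (0.0223).

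Promoters of calcium handling and ion channel genes ranked lower in heart 2 than in heart 1, at a mean percentile of 71.0 against 77.5, and so did those of skeletal muscle genes, at 26.3 against 34.2. Of the calcium handling genes 16 were lower in heart 2 and 3 higher, with Cacna1c, the L-type calcium channel, at 93.9 in heart 1 and 84.6 in heart 2. Among skeletal muscle genes, 9 were lower and 2 higher, with Neb, nebulin, at 44.9 and 27.1, Pax3 at 58.7 and 36.3, and a site of Pax7 at percentile 23.2 in heart 1 without one in heart 2. The difference of each list was outside that of nearly all random lists of like CpG content (adjusted permutation p = 0.00520 for both lists, over 26), which places the lists among other genes and does not compare the animals. Other lists went the same way without being called: 21 of 25 contractile, 13 of 14 neonatal stage, 11 of 13 adult stage and 18 of 22 fatty acid oxidation genes were lower in heart 2 (adjusted permutation p = 0.320, 0.320, 0.356 and 0.407). By summed signal 5 lists were called lower, with cardiac transcription factors, fatty acid oxidation (0.00780 each) and adult stage genes (0.0403) besides the first pair, and with a window of 1000 bp Schwann and autonomic genes were as well (0.0104). Matched on promoter strength as well, neither of the first pair was called (adjusted permutation p = 0.111 and 0.0971), and adult stage genes were (0.0364).

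At the cardiac myosin locus on chromosome 14, both heavy chain genes had accessible promoters. The Myh6 promoter, that of the adult cardiac isoform in mice, held a site from 54966501 to 54967060 at percentile 93.8 in heart 1 and 88.2 in heart 2. The promoter of Myh7, the fetal isoform, held one from 54994301 to 54995180 at 78.4 and 69.8. Myh7 had 4 shared distal sites and Myh6 none, although 7 distal sites of Myh6 were called in heart 2. Sites of both hearts did overlap inside the Myh6 gene, such as 54944997 to 54945363 in heart 1 and 54945041 to 54945340 in heart 2. Such regions lay nearer to the start of another gene or within 2 kb of a start. The count for Myh6 thus follows from the assignment rule and does not mean that its gene body lacked shared sites.

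**Figure D3:**
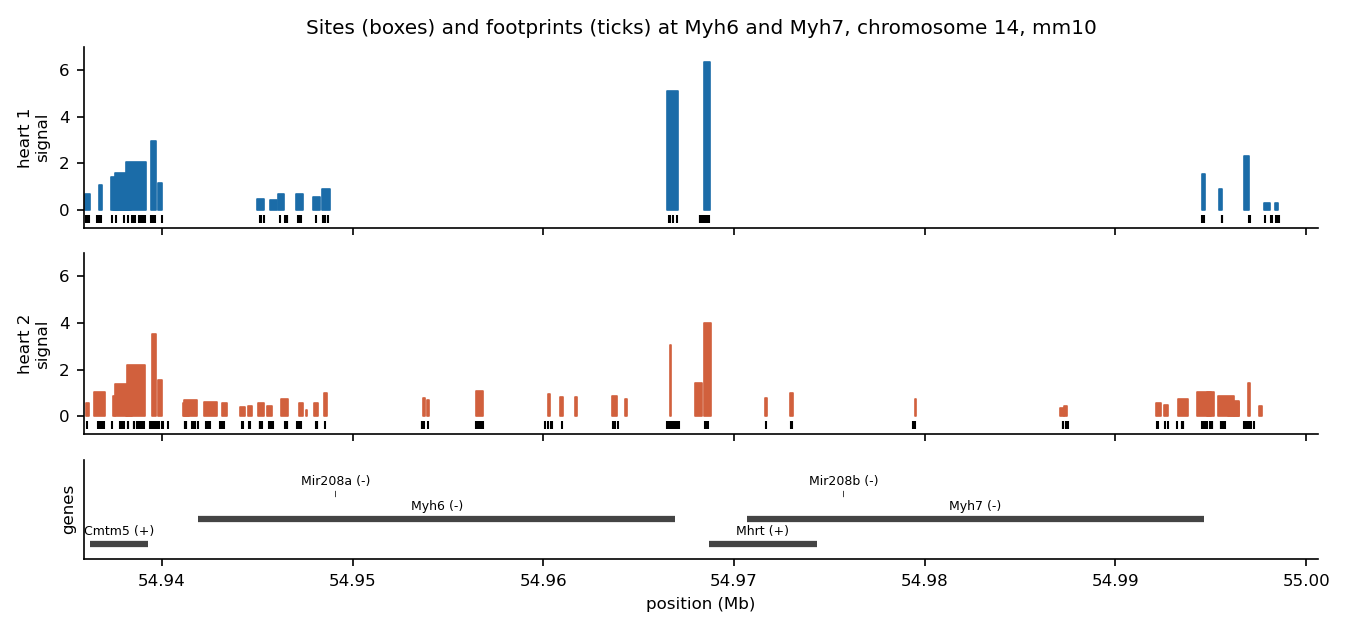
Map of accessible sites (boxes as high as their peak signal) and footprints (black ticks) in heart 1 and heart 2 around Myh6 and Myh7 on chromosome 14 of mm10, position in Mb, with annotated genes and their strands below; genes with Gm names are left out. Heart 1 has 21 sites and 71 footprints in the window and heart 2 has 47 and 160, and the highest signal is 6.34 in heart 1 and 3.98 in heart 2.

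Footprints, short stretches protected from cutting inside accessible DNA, numbered 483073 in heart 1 and 481164 in heart 2, with a median width of 10 bp. Accessible sites contained 85% of them in heart 1 and 86.8% in heart 2. At least 1 footprint was present in 80.8% of the sites of heart 1 and 84.9% of those of heart 2, with 2.31 and 2.36 per site on average. In the weakest decile of sites 28.9% and 40.9% had a footprint, and in the strongest 99.97% and 99.98%. Detection of a footprint grows with the number of cuts at a site and depth is unknown. A weak site without a footprint therefore does not show that no factor was bound. Of the footprints, 54.2% of those of heart 1 and 53.2% of those of heart 2 overlapped one of the other heart. Within shared sites these shares were 61.5% and 59.2%, against 32.2% and 31.9% when footprints were shuffled inside them. An overlap of at least 50% of both footprints was met by 39.1% and 39.2%.

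The motif most concentrated in footprints was that of REST, the repressor of neuronal genes, with a log2 ratio of 6.53 between footprints and the rest of the same sites (6.29 in heart 1, 6.77 in heart 2). In heart 1, 209 of its matches lay in footprints and 15 in the rest, although footprints made up 14.4% of the DNA of the sites. CTCF, the architectural factor, followed with 5.78 (6349 and 809 matches in heart 1), then NRF1, a factor of respiratory genes, with 5.16, NFI with 4.22, CREB/ATF, the cAMP-responsive factors, with 3.85, and RFX with 3.11. FOX at -1.65 (median of its shuffled versions -0.88) and the ERG-type ETS motif at -1.28 (-0.77) were among the lowest. Of other motifs of heart factors, again with the median of the shuffled versions in brackets, MEF2 had 0.25 (-0.89), with 0.76 in heart 1 and -0.26 in heart 2, SRF 0.30 (-0.46), the E-box of HAND and TWIST 0.45 (-0.19) and ESRR 0.09 (-0.46). The nuclear receptor element had -0.16 (-0.22), NKX2-5 -0.32 (-0.53), TBX5 -0.34 (-0.36), MEIS/PBX -0.35 (-0.58) and GATA -0.93 (-0.76), so a value below 0 is common for shuffled motifs as well.

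Of 35 motifs tested, 9 lay above all of up to 50 shuffled versions of themselves, the 6 highest and ETS, the E-box of USF and MEF2. Their p of 0.0196 is the smallest that 50 shuffles can give, and after adjustment over all 38 motifs it was 0.0828, so 0 motifs passed, against 10 at an unadjusted p under 0.05. With up to 1000 shuffles as permutations, a setting chosen after seeing the data and run only for the 31 shorter motifs, 5 passed. These were CTCF, NRF1 and CREB/ATF (adjusted permutation p = 0.0103 each), ETS (0.0155) and YY1 (0.0372). The motifs of REST, NFI and RFX were too long for that setting, so it did not test them. MEF2 had an adjusted p of 0.0619 there, in heart 2 alone it was not above all its shuffles, and in heart 1 alone SRF was, with a log2 ratio of 0.41.

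**Figure D4:**
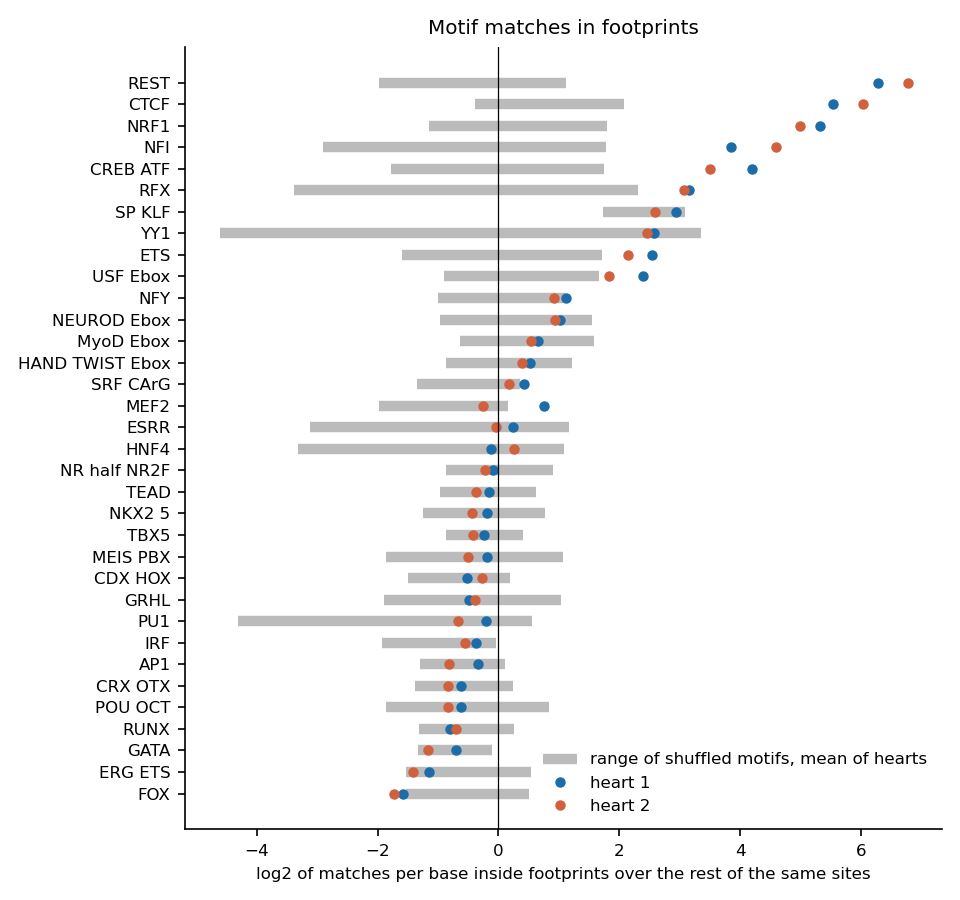
Log2 ratio of motif matches per base inside footprints over the rest of the same sites, for tested motifs in heart 1 and heart 2; grey bars span the shuffled versions of the motif, averaged over the hearts. REST, CTCF and NRF1 lie above 4.99 in both hearts, and GATA, ERG-type ETS and FOX lie below 0 in both.

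At individual promoters, footprints with a motif match in both hearts were found at 8 contractile genes and at 9 cardiac transcription factor genes, with 12 matches in each list. Only motifs of heart factors and those of TEAD, CTCF, NRF1, ETS, CREB/ATF and SP/KLF were searched here, so other motifs are not in these counts. The number of matches expected by chance was not computed. Of the contractile matches 3 were to a motif of a heart factor, the E-box of HAND and TWIST: at Myl2 on chromosome 5 from 122104476 to 122104481, at Tcap, a titin-binding protein, on chromosome 11 from 98383732 to 98383737, and at Csrp3, a muscle LIM protein, on chromosome 7 from 48845767 to 48845772. TEAD motifs lay in footprints at Tpm1 on chromosome 9 from 67049263 to 67049269 and at Ttn on chromosome 2 from 76980413 to 76980419. The footprints at Ttn also held a CTCF match from 76980418 to 76980429 that overlapped the TEAD match, so they cannot be given to either motif. Across all sites TEAD was not concentrated in footprints, with a log2 ratio of -0.27 against a median of -0.32 for its shuffled versions. None of the 12 matches at transcription factor genes was to a heart factor motif. They were 9 matches of SP/KLF, at Gata4, Gata5, Tbx20, Tbx2, Mef2c, Mef2d and Srf, 1 of NRF1 at Mef2a, and 2 of CREB/ATF at Tead1.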

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

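No test was chosen after the results for this part, and both values come from DNA that lies outside the comparisons. In heart 1, stretches at a false discovery rate under 0.05 that touched no accessible site came to 819.6 kb. They numbered 89832 with a median width of 4 bp, against 193 bp for stretches that touched a site. In heart 2 such stretches came to 686 kb and numbered 73086, with a median width of 4 bp, against 176 bp for those that touched a site. DNA under 0.05 that reached beyond the border of a site it touched is not in these values. All DNA under 0.05 came to 64.0 Mb in heart 1 and 54.7 Mb in heart 2, where sites covered 37.3 and 33.6 Mb. Both values stand out because the comparisons use only the called sites, there are no control samples, and any signal there exceeds 0. No explanation was tested.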

How the results depend on the processing

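A setting of up to 1000 shuffles per motif was chosen after seeing the data. Of the comparisons' main values, 49 under an alternative stayed within their interval or within 1.5 times the count, and 24 moved. The share of sites found in the other heart, for heart 1 and heart 2, was 79.7% and 82.0% with the shorter peak list, 87.1% and 88.3% in the stronger 50% of sites, and 65.6% and 66% with a reciprocal overlap of 50%, and with equal numbers of sites it was 76.6% in heart 1. The first 2 settings remove weak sites, which are shared less often, and the reciprocal overlap is a stricter criterion by construction. The share of regions at promoters was 27.4% with a window of 1000 bp and 18.4% with 250 bp, as wider windows hold more, 27.5% with the shorter list, 30.6% in the stronger 50%, and 19.3% to 20.7% in each heart alone. Lists with more accessible promoters numbered 7 with only the 5'-most start, and lists with fewer numbered 2 with CpG-matched random lists. Lists with more distal sites numbered 0 beyond 5 kb from any start. Lists ranked lower in heart 2 numbered 5 by summed signal. The cause was not tested for these 4 counts. Motifs with an adjusted p under 0.05 numbered 5 with up to 1000 shuffles, where more shuffles allow a smaller p and fewer motifs are adjusted for. Sites with a footprint made up 89.9% and 90.4% on the shorter list. Shared footprints made up 39.1% and 39.2% with a reciprocal overlap of 50%, and 61.5% and 59.2% inside shared sites.

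For single lists and motifs, 640 values kept their direction and their side of the threshold, 45 were no longer past it, 20 passed it newly, and 42 changed direction. Of the 42 none was past the threshold as reported, and 1 was with the alternative: the promoter share of epithelial genes minus that of other genes was -55.1 points in the stronger 50% of sites. The cause was not tested for any. The promoter share minus that of other genes also changed sign for neuronal (-16.7) and epicardial genes (-8.82) in the stronger 50%, for epithelial (-24.1), neuronal (-5.74) and epicardial genes (-2.10) with the shorter list, for epithelial genes at 250 bp (-0.903), for epicardial genes with the 5'-most start (-0.131), and against CpG-matched lists for erythroid (8.41) and neuronal genes (-3.41). The log2 ratio of distal sites did so for epicardial (-0.58) and lymphoid genes (-0.10) in the stronger 50%, epicardial (-0.49) and epithelial genes (0.0753) with the shorter list, lymphoid (-0.0215) and skeletal muscle genes (0.12) within 50 kb, and Schwann genes within 500 kb (-0.13) and beyond 5 kb (-0.31). Without matching on length it did so for lymphoid (-1.06), Schwann (-0.00413), hepatocyte (0.0892), neuronal (0.58), epithelial (0.23), germline (-0.39) and housekeeping genes (-0.0339). By summed signal, the promoter percentile minus matched lists did so for calcium handling (-0.736), epicardial (-4.02) and erythroid genes (-1.11). The log2 ratio of footprint motifs above shuffles did so for AP-1 (0.34), NKX2-5 (-0.0454), TBX5 (-0.0965) and CRX/OTX (0.10) widened by 5 bp, MEIS/PBX (-0.48) and GRHL (0.12) in distal sites, and TEAD (-0.0412) with background near footprints. In each heart alone, distal log2 ratios ran from -0.0109 to 0.21 for Schwann and from -0.12 to 0.11 for germline genes, and motif values from -0.35 to 0.0905 for AP-1, -0.0739 to 0.16 for TEAD, -0.45 to 0.0427 for GATA, -0.0919 to 0.12 for TBX5 and -0.00268 to 0.15 for the NR2F half-site. Of the 45, 18 concern distal sites, 17 promoter shares, 6 motifs and 4 promoter strength. The strongest 50% of footprints could not be taken, as their deposited value is constant, so that alternative was not run for footprint motifs or footprints per site. No paired analysis was possible because there is only 1 group. Unknown depth limits what absence of a site means, and with 1 library per animal a difference between hearts cannot be separated from a difference between libraries.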

Other observations

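The tests of motifs in distal regions, of motifs by gene list and of the Y cluster were chosen only after results had been seen, and the other tests below were written beforehand. Of 11 short motifs of heart factors, 3 were past the threshold in distal shared regions against the DNA beside them, and the group as a whole was not tested. MEF2, a factor of muscle genes, had 0.0630 matches per kb in the regions and 0.0169 in flanking DNA, a log2 ratio of 1.89 against a median of -1.20 for its shuffled versions (adjusted permutation p = 0.0123). GATA had a log2 ratio of 0.17 against -0.57 (adjusted permutation p = 0.0211) and the ERG-type ETS motif of endothelial factors 0.83 against 0.11 (adjusted p = 0.0324). The other 8 were not past it: FOX (adjusted permutation p = 0.0553), NKX2-5 (0.190), HAND/TWIST (0.324), SRF (0.326), the NR2F half-site (0.415), MEIS/PBX (0.442), ESRR (0.536) and TBX5 (0.812). CTCF reached 6.25, CREB/ATF 1.87, PU.1, a factor of blood cells, 1.28, AP-1 0.99 and TEAD 0.87 (adjusted permutation p = 0.0123 each), while RUNX, at -0.13 against -0.60 for its shuffles (adjusted p = 0.0369), was past the threshold without being denser than in flanking DNA.

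Motif density in the distal regions of gene lists was compared with random lists for all 63 pairs of 7 lists and 9 motifs. These include pairs whose motif is not that of the list's own cell type, such as MEF2 with hepatocyte genes. None passed, with a lowest adjusted p of 0.315, and 6 pairs had an unadjusted p under 0.05. The ERG-type ETS motif was 1.68 times as dense near endothelial genes as in random lists (permutation p = 0.0124), GATA 1.81 times near calcium handling genes (p = 0.0144) and TBX5 2.04 times near contractile genes (p = 0.0284). The rest of these pairs were sparser than in random lists. They were the ERG-type ETS motif near hepatocyte genes, without a match (permutation p = 0.0150), and near calcium handling genes (0.49 times, p = 0.0252). The last was AP-1 near hepatocyte genes (0.19 times, permutation p = 0.0384). The numbers of matches were small, such as 17 for TBX5 near contractile genes.

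Strong sites called in 1 heart only numbered 196, of which 169 were at promoters. A site of the other heart lay within 200 bp of 96.9% of them without overlap, against 20.8% and 21.7% of shared sites of heart 1 and heart 2 with a neighbour of their own heart that close. Stretches under a false discovery rate of 0.05 in the other heart touched 100% of them, against 11.8% and 23.8% of all unshared sites of heart 1 and heart 2. All unshared sites had a median percentile of 17.8 in both hearts, so this contrast also holds the difference in strength. The neighbours of shared sites, counted within their own heart, are an unlike measure too. These values are consistent with accessible DNA in both hearts that was split into sites at different borders. No biological explanation was tested, since the design has 1 group.

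The strongest shared sites and the sites on chromosome Y were set against the copy number of their sequence. Of the 10 strongest sites, 7 had a median copy number of 31-base words over 1, against 4 of 200 (2%) random sites from the strongest percent, so reads gathered from several copies may raise their signal; Hjurp, Mplkip and Nup107 were single-copy. Of the Y sites, 66.7% had at least 50% of their words on another chromosome, and outside the last cluster 81.7% did. In the cluster from 90717601 to 90744820 the share was 18.2% (4 of 22 sites), with copies on chromosome Y itself not counted. Random shared sites had 1.90% when a second copy on any chromosome was counted, an unlike and wider measure (exact p = 0.00109). That p also treats neighbouring regions of the cluster as independent. The strongest Y site had 91.6% of its words in more than 1 copy and 83.7% on another chromosome. Other strong sites of the cluster, from 90740041 to 90740580 and from 90739541 to 90739840, had 0% on another chromosome. The median over the cluster was 25.1%. The share of 18.2% lay below the bound set for no part of shared sequence, but above random shared sites, so it was read as undecided. Shared sequence thus cannot be told apart from other sources for the cluster as a whole. Its sites were found in heart 1 and heart 2 in 19 and 22 cases. Reads of the CAST genome that differ from the reference were not available, so a strain difference there stays open and untested.

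Calcium handling and skeletal muscle promoters ranked lower in heart 2, by -6.54 and -7.88 percentile points, where random lists of like CpG content moved by -0.561 (95% of them from -3.35 to 2.49) and -0.309 points (-3.97 to 3.91). Random lists matched on promoter strength as well moved by -2.28 (-6.14 to 2.20) and -0.247 points (-6.20 to 5.84), with permutation p = 0.0256 and 0.0112, and over members with a site in both hearts the differences were -4.47 (18 members, permutation p = 0.0464) and -5.72 points (7 members, p = 0.103). The threshold of 0.05 written beforehand made no allowance for lists picked as the most extreme of 26, and adjusted over the lists none of the 4 passed (0.111, 0.0971, 0.151 and 0.267), while adult stage genes, at -3.63 points, passed in both permutation tests (0.0364 and 0.0312) and cardiac transcription factors, at -2.98, in the second (0.0416). On average, the strength-matched lists of skeletal muscle moved by only -0.247 points, so a general shift of promoters of that strength does not make up its -7.88 points. For calcium handling their -2.28 points could make up a part of its -6.54. Beyond these averages it stays undecided whether the 2 lists differ from random lists of that strength, because such random lists spread more widely. Calls in 1 heart only cannot be told apart from a shift of the 2 lists either. For skeletal muscle few members are left. For calcium handling 18 of 20 members are left, where random lists ran from -4.42 to 0.623, and the adjusted permutation p of 0.151 misses the threshold. With 1 library per animal, differences in depth, dissection or cell composition stay open, and no biological explanation was tested.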
